A study of Mus musculus with 12 samples.

How the data were processed

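Total RNA from 12 primary mammary tumours of mice was sequenced, 4 tumours for each of 3 genotypes called WT, C3_KO and S1pr1_KO here. Per the labels' protocols, tumours were kept in RNAlater, RNA was extracted with QIAzol and a sequencing company prepared Illumina libraries. Genotypes came from the genotype label of each sample, and replicates were numbered 1 to 4 within a genotype in accession order, so that a number only names a library. The labels give no batch, litter or pairing and do not say whether the 4 tumours of a genotype came from separate mice. The p-values therefore measure the spread between these samples.

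The authors deposited 2 tables for the whole series with 56860 genes and 12 sample columns each. The first holds raw counts per gene as whole numbers, and no column was left unused. Per the submitters' processing notes, StringTie and genome build GRCm39 (mm39) were named, without a version or a role. The aligner, the counting program and the handling of strand are not given in the sources used here. The totals of the count columns, with M for 1e6 counts, ran from 230.4 to 484.0 M with a median of 361.65 M, and 33159 to 37603 genes had a count above 0. Among counts from 1 to 50, 60.2 to 64.4% of the values were even, as when both mates of a read pair are counted. A fragment then contributes up to a pair of counts, and the totals overstate the number of fragments. The count of Gm10925, a nuclear copy of a mitochondrial gene, was 99.0 to 100.3% of the count of mt-Atp6 in each library, as when reads that match several places are counted at each of them. Levels of pseudogenes, near-identical paralogs and overlapping or antisense genes are uncertain for this reason. The second table holds FPKM values from the authors. All 682320 deposited FPKM values equalled the count times 1000000000 divided by the deposited gene length and by the column total, within a relative tolerance of 0.0001, so the FPKM table holds no measurement beyond the counts. The deposited length column is a gene length in bases.

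Gene names were used as deposited, including 1606 genes named by an Ensembl identifier. The gene annotation at hand belongs to an older build than the authors' build. It was used only for biotypes and for which genes are neighbours, after 49198 names matched by symbol and 12 by identifier, and no coordinates are given.

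Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filter on low counts, which left 30660 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood F-test with a robust estimate of the spread was fitted to all 12 libraries with a mean per genotype, which left 9 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes under an adjusted p of 0.05 were called. The common biological coefficient of variation was 0.564. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Levels are given in CPM, counts per 1e6 counts of a library scaled with TMM factors, as mean ± SD of 4 libraries.

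A total of 37 gene lists with 706 genes, 705 of them in the table, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists. Each list was tested again with a correlation estimated from the data and with fry, a self-contained rotation test, both from limma 3.58.1. The lists covered complement, sphingosine-1-phosphate metabolism and receptors, IL-6 and STAT3, the inflammasome, chemokines, interferon response, both classes of antigen presentation, immune checkpoints, immune, endothelial, mural and stromal cell types, matrix proteases, epithelial-mesenchymal transition, luminal and basal epithelium, milk proteins, cell cycle, hypoxia, lipid synthesis, unfolded protein response, immediate early genes, and adipocyte, muscle, skin, Schwann, salivary, red blood cell, mitochondrial and ribosomal genes. Per list, members were also adjusted over the list alone. A list score is the mean log2 CPM of its measured members, with a prior count of 2.

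The genes named were chosen by a fixed rule. C3 and S1pr1 were always named. For each comparison with WT, up to 12 genes called higher and 12 called lower, not overlapping between groups and with an average log2 CPM of at least 1, were to be named, and up to 6 in each direction between the knockouts. Where fewer than 6 qualified, genes of smallest p were added up to 6 as values that did not pass. Predicted genes, pseudogenes and antigen receptor segments were counted and not named by this rule. Of each list, up to 4 members called were to be named, and of a list moved by camera with no member called, up to 2 of the members of smallest p were given. The groups, lists, tests, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise. The 2 alternatives added after the data were seen left out predicted genes and pseudogenes, or left out C3_KO replicate 3 with S1pr1_KO replicates 1 and 4, which were rich in milk or salivary transcripts. The second of these leaves only S1pr1_KO replicates 2 and 3 in that group. The covariance was called moved when it shifted by over 0.11, the SD of its leave-one-out values. This bound was chosen after the SD of the simulated covariances, 0.0062, had been tried and had called nearly every alternative moved.

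Alternatives comprised DESeq2 1.42.0, limma-voom with sample quality weights, other size factors (RLE and upper quartile), the 20 most abundant genes left out, no filter on low counts, a filter of CPM of at least 1 in 4 samples, only the 2 groups compared, no robust estimate, a fold minimum of log2 1, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Each library was also left out in turn. DESeq2's independent filtering leaves some adjusted p-values undefined, and these were kept undefined. Both comparisons with WT share the WT libraries, so the covariance of their fold changes was set beside 20 simulations of unchanged groups and recomputed with the WT libraries split between the comparisons.

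The methods were tested on simulated data with changed genes of known fold, drawn with the levels and spread of these libraries. For C3_KO against WT, edgeR recovered 1.5% of the genes simulated at fold 2, 59.7% at fold 4 and 100% at fold 8, with 3 false calls among 29879 genes. For S1pr1_KO against WT, it recovered 6.0% at fold 2, 70.1% at fold 4 and 90.9% at fold 8, with 4 false calls among 29879 genes. DESeq2 recovered 29.9% at fold 2 and 77.6% at fold 4 for C3_KO against WT with 82 false calls among 30660 genes, and 22.4% and 91.0% for S1pr1_KO against WT with 55 false calls. A list of 25 genes shifted by log2 1 in simulated S1pr1_KO libraries was recovered at an adjusted p of 1.87e-20 with the preset correlation, 1.40e-04 with an estimated correlation and 1.49e-04 with fry. Each gene was drawn independently, so the members of this list, the fibroblast and matrix genes, were not correlated. In the data, the estimated correlation of the same list was 0.493 in S1pr1_KO against WT. The recovery therefore does not show what the list tests can find in these data. In these simulations, changes of fold 2 were mostly below what the gene test could call. The recovery of larger folds may not carry over to the data, where single libraries stood apart. Meis1, at log2 -3.77 in C3_KO against WT with no overlap between groups, was not called (edgeR adjusted p = 0.765). A gene that was not called can therefore still differ by a large fold.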

Results

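RNA was measured in primary mammary tumours that arise in mice with the MMTV-PyMT transgene, which expresses the polyoma middle T oncogene in mammary epithelium. Tumours were taken at 4.5 months from 3 strains bred separately. WT tumours carried MMTV-Cre beside the oncogene, per the design text, while the strain label of these samples names the oncogene alone. C3_KO tumours carried MMTV-Cre with a modified C3 allele, and S1pr1_KO tumours carried MMTV-Cre with floxed S1pr1. The MMTV promoter drives Cre mainly in mammary epithelium, so other cells of a tumour can keep the targeted gene. The question was how conditional loss of complement component C3 or of the sphingosine-1-phosphate receptor S1pr1 affects the tumours. Each genotype had 4 libraries. Total counts, with M for 1e6 counts, ran from 327.1 to 484.0 M in WT, 237.1 to 424.6 M in C3_KO and 230.4 to 380.3 M in S1pr1_KO. Correlations between libraries lay between 0.961 and 0.993 across genes, which are not independent replicates, with a median of 0.98 within and 0.976 between genotypes. On the first principal component, with 28.7% of the variance, S1pr1_KO replicates 1, 2 and 4 lay at 118.4, 128.7 and 77.7. S1pr1_KO replicate 3 lay at -102.1, nearest to WT replicate 1 at -114.2.

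The targeted genes were examined first. C3, the central component of the complement cascade, stood at 101 ± 58.2 CPM in WT and 59.7 ± 17.6 CPM in C3_KO (SD, n = 4). The log2 fold change was -0.76 with an SE of 0.49, less than the spread allowed to be called (edgeR adjusted p = 0.765). C3 levels of the C3_KO libraries were 47.8, 74.5, 41.6 and 75.1 CPM, and those of the WT libraries were 182, 89.2, 90.3 and 43.3 CPM. Without WT replicate 1 the log2 fold change was -0.32. C3 was 163 ± 94.5 CPM in S1pr1_KO (SD, n = 4). S1pr1, a receptor abundant on endothelial cells, stood at 5.21 ± 2.63 CPM in WT, 4.64 ± 2.35 CPM in S1pr1_KO and 7.40 ± 1.75 CPM in C3_KO (SD, n = 4). In S1pr1_KO against WT, its log2 fold change was -0.17 with an SE of 0.43 (edgeR adjusted p = 0.874), and a difference was not detectable. The direction turned to 0.39 with limma-voom, to 0.01 on the FPKM scale, to 0.12 without WT replicate 2, to 0.08 without S1pr1_KO replicate 3 and to 0.01 without S1pr1_KO replicate 4. It was -0.49 without S1pr1_KO replicate 2, -0.37 without WT replicate 3, -0.31 without WT replicate 4 and -0.01 without WT replicate 1. Gene counts from whole tumours do not tell which cells the reads came from or whether an exon was lost, so these levels check the genotype labels only in part.

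**Figure D1:**
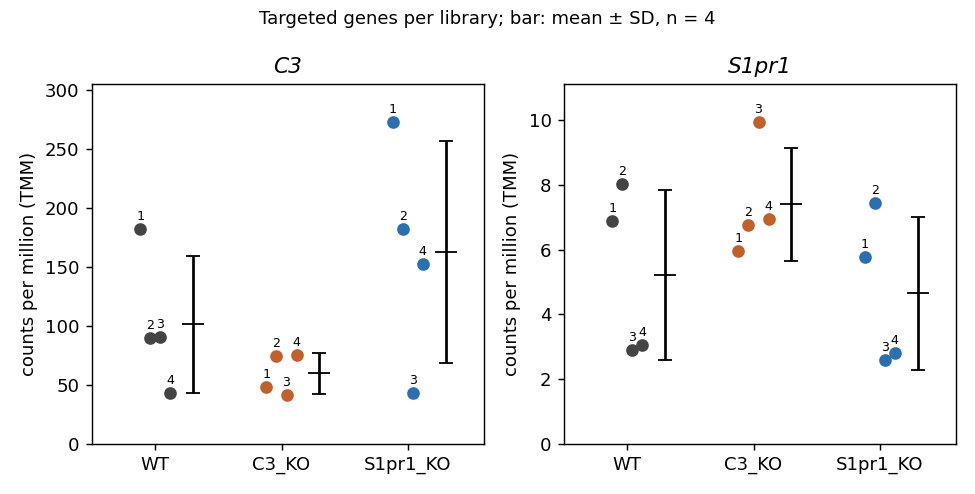
Levels of C3 and S1pr1 per library, in TMM-scaled CPM on linear axes from 0, with the replicate number above each point and the mean ± SD of 4 libraries as a bar beside each group. The C3_KO libraries lie between 41.6 and 75.1 for C3, within the WT range of 43.3 to 182 except for replicate 3, and S1pr1 overlaps between all 3 groups.

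In C3_KO against WT, no gene was called, and the values of smallest p came from genes of varied function. Cdhr1, a cadherin known from photoreceptors, was 3.77-fold higher at 95.3 ± 20.3 against 25.3 ± 5.97 CPM (SD, n = 4), with every C3_KO library above every WT library. Its log2 fold change was 1.91 with an SE of 0.27, the smallest p of this comparison (edgeR adjusted p = 0.227). Other genes with every C3_KO library above every WT library were Adamtsl2, a secreted matrix glycoprotein, at log2 1.68, Pinc, a noncoding RNA of the mammary gland, at 2.63, and the D-aspartate oxidase gene Ddo at 1.76. Col4a6, a basement membrane collagen chain, stood at log2 1.40 and Bmp1, which processes procollagens, at 0.78. In the other direction, Glo1, which detoxifies methylglyoxal, stood at 66.2 ± 11.4 against 126 ± 26.4 CPM (SD, n = 4), a log2 fold change of -0.93 with an SE of 0.21. The homeobox gene Meis1 was at log2 -3.77, the centromere protein gene Cenpx at -1.19, Ten1 of a telomere-binding complex at -1.15, Engase at -1.06 and the dynein light chain gene Dynlt1b at -1.25. Dynlt1b has near-identical copies and Glo1 has a pseudogene with a parallel pattern, given below, so their reads are uncertain. None of these 12 genes passed, with edgeR adjusted p-values from 0.227 to 0.765. Of these genes, Pinc, Bmp1 and Meis1 overlapped between S1pr1_KO and WT, and the others parted S1pr1_KO from WT as well.

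Among 30660 genes tested in C3_KO against WT, edgeR called 0. At an unadjusted p under 0.05 there were 1909 genes, 1109 higher and 800 lower, where 1533 are expected by chance. Groups did not overlap for 931 genes, or 3%, where chance gives 2.9%. DESeq2 called 84 genes, 29 higher and 55 lower, limma-voom with quality weights called 5, and limma on log2(FPKM + 1) called 1. In the simulated data DESeq2 made 82 false calls in this comparison, so its count here is no evidence of change. The edgeR count was 8 without S1pr1_KO replicate 3, which is not in the comparison but shares its estimate of the spread, and 3 without C3_KO replicate 4. In the refit without S1pr1_KO replicate 3, Cdhr1 passed with an edgeR adjusted p of 0.0221, within a range of 1.48e-05 to 0.991 over its 26 alternatives.

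Of the 37 lists, camera with the preset correlation moved 9 in C3_KO against WT, 5 higher and 4 lower, and none held with an estimated correlation, where the lowest adjusted p was 0.991. Ribosomal protein genes were lower in 30 of 30 members, with a median log2 of -0.59 (camera adjusted p = 6.63e-13; adjusted p = 0.991 with an estimated correlation). Rpl10a was at log2 -0.53 and Rps19 at -0.65. Cell cycle genes were lower in 26 of 30 (camera adjusted p = 1.40e-04), among them the survivin gene Birc5 at log2 -1.15 and the thymidylate synthase gene Tyms at -0.39. Genes of MHC class I presentation were lower in 14 of 15 (camera adjusted p = 1.40e-04), with the immunoproteasome genes Psmb8 at log2 -0.88 and Psmb9 at -0.77. MHC class I scores, in mean log2 CPM, were 8.35, 6.27, 6.13 and 7.67 in C3_KO replicates 1 to 4 against 7.45 to 8.36 in WT. Only replicates 2 and 3 lay below the WT range. Blood endothelial markers were higher in 20 of 21 (camera adjusted p = 3.18e-05), with Mmrn2 at log2 0.75 and the VEGF receptor gene Kdr at 0.72. Fibroblast and matrix genes were higher in 20 of 25 (camera adjusted p = 1.89e-04), with Col6a3 at log2 1.26 and Col6a1 at 0.77, and adipocyte markers in 18 of 19 (camera adjusted p = 5.67e-04), with the fatty acid transporter gene Cd36 at 2.01 and Acsl1 at 0.68. No member of these 6 lists passed when adjusted over the list alone. All 6 lists, like the 3 below, had an adjusted p of 0.991 with an estimated correlation. The cell cycle call was lost without C3_KO replicate 4 (camera adjusted p = 0.0702), and without C3_KO replicate 2 those of MHC class I (0.0547), adipocyte markers (0.0527) and fibroblast and matrix genes (0.0507).

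Of the remaining 3 lists, the milk and skin calls rested on C3_KO replicate 3, and the salivary call was lost in several refits. Milk protein genes were higher in 16 of 20 members, with a median log2 of 2.04 (camera adjusted p = 1.46e-04; adjusted p = 0.991 with an estimated correlation). Adjusted over the list alone, 10 of the 20 passed as higher, among them Csn1s2b at log2 6.12 and the lactose synthase component Lalba at 3.15. Their level was highest in C3_KO replicate 3, where the casein genes Csn1s1 and Csn2 reached 29170 and 24190 CPM against at most 106.9 and 74.7 CPM in the WT libraries. Without C3_KO replicate 3 the call was lost (camera adjusted p = 0.531). Markers of skin keratinocytes and hair were higher in 17 of 17 (camera adjusted p = 1.67e-04), with Krt10 at log2 3.29 and Flg at 4.71, and were lost without the same library (camera adjusted p = 0.210). Without the 3 libraries rich in milk or salivary transcripts, neither the milk (camera adjusted p = 0.502) nor the skin list (0.184) was called. Salivary gland markers were lower in 8 of 11 (camera adjusted p = 0.0300), with Smr2 at log2 -5.35 and Dcpp2 at -6.33. Smr2 was 87.1 CPM in WT replicate 4 and at most 5.50 CPM in the other WT libraries. Dcpp2 was 6.95 to 38.7 CPM in WT and 0.0095 to 0.619 CPM in C3_KO. Salivary scores, in mean log2 CPM, were 2.22, -1.44, -1.95 and -1.77 in C3_KO replicates 1 to 4 against 2.18, -0.67, 1.97 and 1.47 in WT. That call was lost on log2(FPKM + 1) (camera adjusted p = 0.0690), without WT replicate 1 (0.133) and without C3_KO replicates 2 (0.276), 3 (0.150) or 4 (0.113). Over the list alone, 1 of 24 matrix protease genes also passed, the collagenase gene Mmp13 at log2 3.30, at 38.3 CPM in C3_KO replicate 3 and 10.1 CPM in C3_KO replicate 2. The number of moved lists was 16 without C3_KO replicate 1 and 6 without C3_KO replicate 2.

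The other 28 lists were not moved in C3_KO against WT. Complement genes were higher in 24 of 31 with a median log2 of 0.38 (camera adjusted p = 0.168), and sphingosine-1-phosphate genes in 20 of 29 with a median of 0.14 (camera adjusted p = 0.512). Interleukin-6 and STAT3 genes were higher in 16 of 24, inflammasome genes in 14 of 18, chemokines in 16 of 25 and neutrophil markers in 10 of 13 measured, the last with a median log2 of 1.10 (camera adjusted p = 0.166). The neutrophil score, in mean log2 CPM, was 2.03 in C3_KO replicate 3 and -1.14 to -0.3 in the other C3_KO libraries against -0.87 to 0 in WT, so this value rests on a single library. The median and the test differed in sign for the interferon response, B cell, T cell, skeletal muscle and immediate early lists. The median and the mean differed in sign for MHC class II presentation and pericyte markers.

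In S1pr1_KO against WT, the differences in list scores were carried by some of the libraries, and their calls depended on the test. Scores of the adipocyte, B cell, dendritic cell, endothelial, fibroblast and complement lists lay above all 4 WT libraries in S1pr1_KO replicates 1 and 2 only. Complement scores, in mean log2 CPM, were 4.48, 4.32, 3 and 3.71 in S1pr1_KO replicates 1 to 4 against 3 to 3.79 in WT. B and plasma cell scores, in mean log2 CPM, were 4.22, 3.13, -0.92 and -0.28 in S1pr1_KO replicates 1 to 4 against -0.7 to 0.24 in WT, and adipocyte scores 6.14, 5.29, 1.84 and 3.01 against 1.07 to 3.81. Adipocyte markers were higher in 19 of 19 members, with a median log2 of 2.30, including the thermogenic gene Ucp1 at 7.45 and the adrenergic receptor gene Adrb3 at 3.94 (camera adjusted p = 5.08e-07). Ucp1 was 48.3 CPM in S1pr1_KO replicate 1 and 0.0702 to 0.127 CPM in the other S1pr1_KO libraries, and its log2 fold change was 0.70 without S1pr1_KO replicate 1. B and plasma cell markers were higher in 20 of 20, with a median log2 of 3.53 (camera adjusted p = 2.49e-06). Adjusted over the list alone, 13 of the 20 passed as higher, among them Blk, a B cell kinase, at log2 4.14 and the inhibitory receptor gene Cd22 at 3.25. Dendritic cell markers were higher in 12 of 13 (camera adjusted p = 2.28e-04), and 7 passed over the list alone, such as the chemokine gene Ccl22 at log2 2.16 and Cd209a at 1.75. Blood endothelial markers were higher in 20 of 21, with Ptprb at log2 1.24 and Mmrn2 at 0.93 (camera adjusted p = 2.49e-06). Fibroblast and matrix genes were higher in 23 of 25, with Col6a1 at log2 0.92 and Col6a3 at 1.22 (camera adjusted p = 1.04e-04). Complement genes were higher in 24 of 31, with the complement receptor gene Cr2 at log2 5.54 and Masp1 at 0.82 (camera adjusted p = 0.00235). For each of these lists the adjusted p was 0.822 with an estimated correlation. On log2(FPKM + 1), the B and plasma cell list (camera adjusted p = 0.273) and the dendritic cell list (0.0653) were not called.

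T cell markers were higher in 19 of 20, with Ccr7 at log2 1.96 (camera adjusted p = 0.00137; adjusted p = 0.839 with an estimated correlation). NK and cytotoxic cell markers were higher in 14 of 16, with Klre1 at log2 1.82 and Klrd1 at 1.31 (camera adjusted p = 0.0209; adjusted p = 0.839 with an estimated correlation). Macrophage and monocyte markers were higher in 17 of 22, with Adgre1 at log2 1.24 and Marco at 6.80 (camera adjusted p = 0.0206; adjusted p = 0.822 with an estimated correlation). Genes of MHC class II presentation were higher in 11 of 11, of which H2-Ob, expressed in B cells, passed over the list alone at log2 3.48 (camera adjusted p = 0.0298; adjusted p = 0.839 with an estimated correlation). Ciita, the regulator of this gene class, stood at log2 0.56. The T cell call was lost without S1pr1_KO replicate 1 (camera adjusted p = 0.191), and the NK call without S1pr1_KO replicate 1 (0.223) or WT replicate 3 (0.0591). The macrophage call was lost without WT replicate 3 (0.120), and the MHC class II call without WT replicate 3 (0.189), S1pr1_KO replicate 1 (0.159) or S1pr1_KO replicate 3 (0.0555). On log2(FPKM + 1), the T cell (camera adjusted p = 0.133), NK (0.330) and MHC class II lists (0.0653) were not called, and with the CPM filter the NK list was not (0.122). Without the 3 libraries rich in milk or salivary transcripts, the NK and macrophage lists were not called (camera adjusted p = 0.0694 for both). Levels differed widely within S1pr1_KO. Adipoq was 52.7, 50, 1.03 and 5.29 CPM in replicates 1 to 4, Cr2 12.8, 6.68, 0.0497 and 0.0818 CPM, and Marco 9.00, 2.66, 0 and 0.0223 CPM. Salivary gland markers were higher in 10 of 11 (camera adjusted p = 0.00230; adjusted p = 0.822 with an estimated correlation) and 8 passed over the list alone. Among them, Amy1 was 28670 CPM in S1pr1_KO replicate 1 and 1161 CPM in replicate 4, and Prb1 730 and 11.0 CPM. Without C3_KO replicate 3 and these 2 libraries, the salivary list turned in direction (camera adjusted p = 0.416).

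Ribosomal protein genes were lower in 30 of 30 members in S1pr1_KO against WT, with a median log2 of -0.79 (camera adjusted p = 3.03e-14; adjusted p = 0.822 with an estimated correlation). Adjusted over the list alone, 3 of the 30 passed as lower, Rpl11 at log2 -0.95, Rpl4 at -0.85 and Rpl10a at -0.80. Rpl4 stood at 1010 ± 110 CPM in S1pr1_KO against 1820 ± 232 CPM in WT (SD, n = 4). Ribosomal scores were 9.38, 8.91, 10.35 and 9.04 in S1pr1_KO replicates 1 to 4 against 10.05 to 10.47 in WT, so that S1pr1_KO replicate 3 lay within the WT range. The 4 libraries with the lowest totals, C3_KO replicate 4 with 237.1 M and S1pr1_KO replicates 1, 2 and 4 with 248.7, 284.1 and 230.4 M, had the 4 lowest ribosomal scores, so depth and genotype cannot be told apart here. Cell cycle scores were 4.47, 4.85, 5.52 and 5.18 against 5.49 to 5.86 in WT. Cell cycle genes were lower in 30 of 30, with Birc5 at log2 -1.60 and Tyms at -0.77 (camera adjusted p = 2.49e-06; adjusted p = 0.822 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13, with mt-Co2 at log2 -0.93 and mt-Atp6 at -0.74 (camera adjusted p = 0.0156; adjusted p = 0.839 with an estimated correlation). The mitochondrial call was lost on log2(FPKM + 1) (camera adjusted p = 0.0524), with the CPM filter (0.0673), without WT replicate 2 (0.126), S1pr1_KO replicate 2 (0.123) or S1pr1_KO replicate 4 (0.0656). In total camera moved 14 lists, 11 higher and 3 lower. None held with an estimated correlation (lowest adjusted p 0.822), and none passed with fry.

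**Figure D2:**
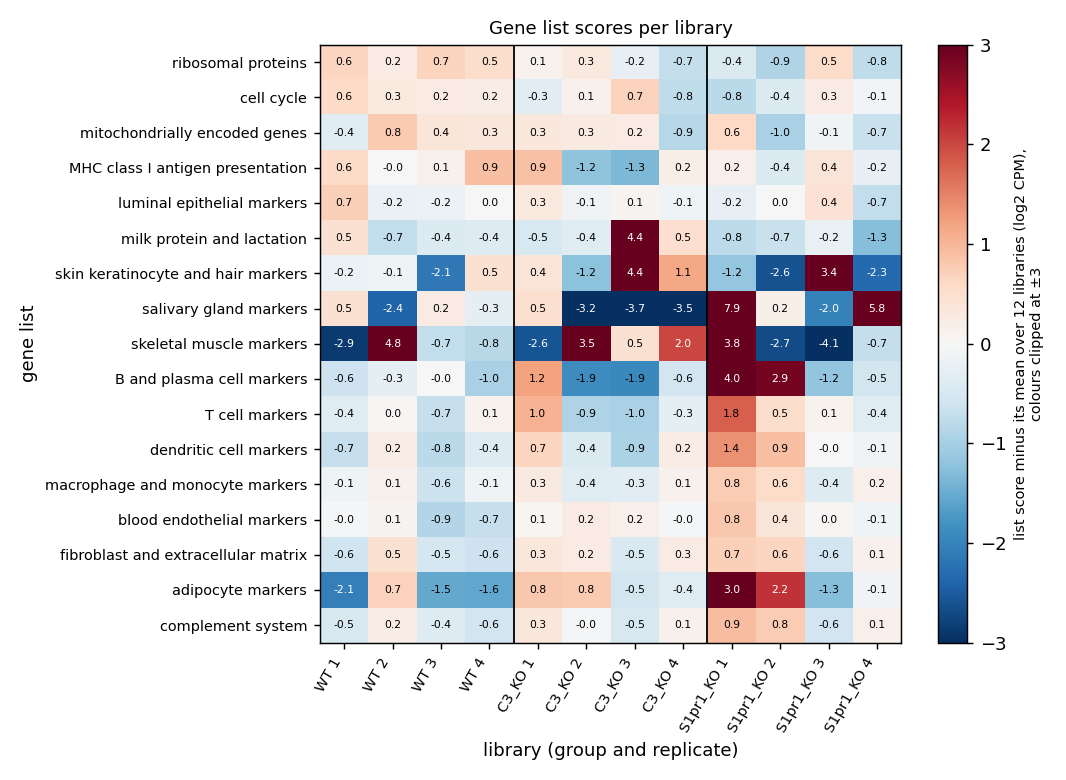
Scores of 17 gene lists per library, each the mean log2 CPM of the list's measured members minus its mean over the 12 libraries, with colours clipped at ±3 and values printed in the cells. B and plasma cell and adipocyte scores are high in S1pr1_KO replicates 1 and 2, salivary scores in S1pr1_KO replicates 1 and 4, and milk and skin scores in C3_KO replicate 3.

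Of single genes in S1pr1_KO against WT, Cyp2f2, a cytochrome P450 gene, was 13.8-fold higher at 34.5 ± 31.0 against 2.5 ± 0.686 CPM (SD, n = 4; edgeR adjusted p = 0.0756). It was 75.4, 17, 5.02 and 40.4 CPM in S1pr1_KO replicates 1 to 4, highest in replicates 1 and 4, which were rich in salivary transcripts. The sialyltransferase gene St3gal1 was 2.44-fold higher at 75.9 ± 19.0 against 31.2 ± 6.40 CPM (SD, n = 4; edgeR adjusted p = 0.106). Ahnak2 was at log2 0.85, Teddm2 at 2.52, the microRNA gene Mir8114 at 2.63 and Tpm3-rs7, a copy related to a tropomyosin gene and so of uncertain reads, at 2.08. Teddm2 and Mir8114 rose and fell together, at 15.2 and 12.9 CPM in S1pr1_KO replicate 2 and 1.24 and 0.891 CPM in WT replicate 3. They may hold the same reads and cannot be taken as separate results. Glo1 was lower at 53.4 ± 7.64 against 126 ± 26.4 CPM (SD, n = 4), a log2 fold change of -1.24 with an SE of 0.21 (edgeR adjusted p = 0.0615). Its reads are uncertain, as its pseudogene had a parallel pattern. Dynlt1b and its near-identical relative Dynlt1c were at log2 -1.86 and -1.39. Ankrd1, a target of YAP signalling, was at log2 -2.51, the tRNA guanylyltransferase gene Thg1l at -1.17 and the heme-binding protein gene Hebp1 at -1.21. Except for Tpm3-rs7, whose S1pr1_KO and WT values overlapped, all 4 S1pr1_KO libraries lay on 1 side of all 4 WT libraries for these 12 genes. None passed, with edgeR adjusted p-values from 0.0610 to 0.150.

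Among 30660 genes in S1pr1_KO against WT, edgeR called 0, and 4743 genes, or 15.5%, had an unadjusted p under 0.05, 2359 higher and 2384 lower. The lowest edgeR adjusted p was 0.0536, for the predicted gene Gm29718. Under an adjusted p of 0.1 lay 42 genes, 38 of them lower and 36 of them predicted genes, pseudogenes or receptor segments. Groups did not overlap for 2323 genes, or 7.6%, where chance gives 2.9%. DESeq2 called 901 genes, 554 higher and 347 lower, and limma-voom with quality weights called 7828, 3391 higher and 4437 lower. In the simulated data DESeq2 made 55 false calls in this comparison. Other settings called mostly lower genes, with 1 higher and 67 lower where only the 2 groups were compared, 1 and 22 with the CPM filter, 1 and 9 with no filter, 0 and 41 on log2(FPKM + 1) and 0 and 39 on log2(FPKM + 0.1). Without S1pr1_KO replicate 3, edgeR called 1330 genes, 486 higher and 844 lower. That refit and DESeq2 shared 461 genes, and predicted genes, pseudogenes or receptor segments made up 598 of the 1330 and 546 of the 901. Of the 30660 genes tested in the main fit, 12955 were of these kinds. The share in the refit was near this, and that among the 42 genes under an adjusted p of 0.1 was above it. DESeq2 tested 45227 genes, for which the share is not given here. In the refit, Cyp2f2 passed at log2 4.19 (edgeR adjusted p = 0.00383, within 9.08e-07 to 0.719 over its 26 alternatives) and Glo1 at log2 -1.24 (edgeR adjusted p = 0.0454, within 8.07e-04 to 0.719). Ribosomal protein genes fell in 20 of 30 in that refit, with a median log2 of -1.18 and a fry adjusted p of 0.0318, while the adjusted p was 0.734 with an estimated correlation. B and plasma cell markers rose in 7 of 20, and 18 lists were moved. Those gained there were the skin (camera adjusted p = 0.0131), hypoxia (0.00785), luminal (0.0279) and MHC class I lists (0.0419) as lower and the checkpoint list (0.0419) as higher, and the MHC class II list was lost (0.0555). None of the gained lists held with an estimated correlation (adjusted p = 0.734 to 0.743) or with fry. Counts without other libraries were 32 without C3_KO replicate 4, of which 30 were lower, and 9 without C3_KO replicate 1, 2 without C3_KO replicate 3 and 1 without S1pr1_KO replicate 2, all lower.

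The remaining lists were not moved in S1pr1_KO against WT. Sphingosine-1-phosphate genes were higher in 17 of 29 with a median log2 of 0.08 (camera adjusted p = 0.591), with the kinase gene Sphk1 at -1.19 and the receptor gene S1pr4 at 1.51 as members of low p, named after their values were seen. Immune checkpoint genes were higher in 14 of 20 (camera adjusted p = 0.0545), inflammasome genes in 14 of 18, lymphatic endothelial markers in 6 of 8, Schwann cell markers in 6 of 10 and interferon response genes in 15 of 25. Interleukin-6 and STAT3 genes were higher in 14 of 24, chemokines in 13 of 25, neutrophil markers in 9 of 13, pericyte markers in 7 of 12 and lipid synthesis genes in 13 of 23. Genes of epithelial-mesenchymal transition were higher in 12 of 20, of the unfolded protein response in 10 of 21, immediate early genes in 10 of 20 and skin markers in 15 of 17. The skin score was 2.85 in S1pr1_KO replicate 3 and -3.19 to -1.72 in the other S1pr1_KO libraries against -2.71 to -0.11 in WT. Without S1pr1_KO replicate 3 the skin list turned to lower, with a median log2 of -1.75 (camera adjusted p = 0.0131). MHC class I genes were lower in 13 of 15 (camera adjusted p = 0.0644), luminal markers in 14 of 22, basal markers in 11 of 18, milk genes in 13 of 20 and hypoxia genes in 19 of 24. Without S1pr1_KO replicate 3 the median log2 of hypoxia genes was -0.74 and the list was called lower (camera adjusted p = 0.00785). Matrix proteases were lower in 14 of 24, muscle markers in 17 of 18 and red blood cell markers in 8 of 8. The muscle score was 7.69 in WT replicate 2 and 0 to 2.14 in the other WT libraries, and 6.71, 0.18, -1.27 and 2.15 in S1pr1_KO replicates 1 to 4. The median, mean and test differed in sign for pericyte, unfolded protein response and immediate early genes.

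The knockouts were also compared directly, which has no WT library on either side. The size of the differences in B cell, salivary and milk transcripts came mostly from 1 or 2 libraries each. Of S1pr1_KO replicates 1 to 4, B and plasma cell scores were 4.22, 3.13, -0.92 and -0.28 and salivary scores 9.63, 1.91, -0.3 and 7.49. Milk scores were 10.06 in C3_KO replicate 3 against 5.22 to 6.21 in the other C3_KO and 4.42 to 5.48 in the S1pr1_KO libraries. B and plasma cell markers were higher in 20 of 20, with a median log2 of 3.11, and 12 passed over the list alone, including Cd22 at 3.05 and Blk at 3.16 (camera adjusted p = 2.53e-20; adjusted p = 0.490 with an estimated correlation). Salivary markers were higher in 11 of 11 and 9 passed over the list alone, with Amy1 at log2 9.09 and Dcpp2 at 10.65 (camera adjusted p = 5.23e-14; adjusted p = 0.490 with an estimated correlation). Milk protein genes were lower in 20 of 20 and 10 passed over the list alone, with Csn1s2a at log2 -11.40 and Csn1s2b at -6.44 (camera adjusted p = 1.20e-10; adjusted p = 0.585 with an estimated correlation). T cell markers were higher in 20 of 20, with Cd4 at log2 1.18 (camera adjusted p = 5.82e-09; adjusted p = 0.585 with an estimated correlation), and dendritic cell markers in 11 of 13, with Ccl22 at 1.81 and Ccr7 at 1.54 (camera adjusted p = 8.75e-05; adjusted p = 0.602 with an estimated correlation). These 5 lists were called in each of the 12 fits that left out a library, but without the 3 libraries rich in milk or salivary transcripts together the milk (camera adjusted p = 0.184) and dendritic cell lists (0.0795) were not. C3 itself was 2.72-fold higher in S1pr1_KO than in C3_KO, at log2 1.44 with an SE of 0.50, and did not pass (edgeR adjusted p = 1). S1pr1 was at log2 -0.67 with an SE of 0.43 (edgeR adjusted p = 1).

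Camera moved 15 further lists between the knockouts, none of which held with an estimated correlation, where adjusted p-values ran from 0.585 to 0.729 for these lists, and none of which was called in all fits that left out a library. Higher in S1pr1_KO were adipocyte markers in 19 of 19, with Ucp1 at log2 5.04 and Pparg at 1.35, MHC class II genes in 11 of 11, with H2-Ob at 3.18 and H2-Oa at 1.41, and NK markers in 13 of 16, with Prf1 at 1.14 and Tbx21 at 0.82. Macrophage markers were higher in 18 of 22, with Marco at log2 5.32 and Cd14 at -0.70, complement genes in 26 of 31, with Clu at -1.13, and checkpoint genes in 14 of 20, with Btla at 2.19 and Pdcd1lg2 at 1.35. Endothelial markers were higher in 19 of 21, with Ptprb at log2 0.60 and Sox17 at 0.61, and interferon genes in 15 of 25, with Rtp4 at 0.30 and Ifit3 at -0.54. Lower in S1pr1_KO were red blood cell genes in 8 of 8, with Hbb-bt at log2 -1.76, skin markers in 13 of 17, with Lor at -2.99 and Flg2 at -7.12, and hypoxia genes in 19 of 24, with Egln3 at -0.87 and P4ha1 at -0.46. Cell cycle genes were lower in 29 of 30, with Tyms at log2 -0.38 and Ccne2 at -0.40, ribosomal protein genes in 27 of 30, with Rpl11 at -0.40 and Rpl5 at -0.32, luminal markers in 16 of 22, with Muc1 at -1.09 and Aldh1a3 at -1.41, and muscle markers in 13 of 18, with Myh2 at -0.98 and Actn3 at -0.99. Several of these values turned in direction when libraries were left out. Ucp1 was at log2 -1.74 without S1pr1_KO replicate 1 and -2.18 without the 3 libraries rich in milk or salivary transcripts, Ifit3 at 0.23 without C3_KO replicate 1, Aldh1a3 at 0.14 without C3_KO replicate 3 and Actn3 at 0.56 without C3_KO replicate 2. Cell cycle genes turned without C3_KO replicate 3 or S1pr1_KO replicate 1, hypoxia genes without C3_KO replicate 3 and interferon genes without C3_KO replicate 2 or 3. Without the 3 libraries rich in milk or salivary transcripts, cell cycle (camera adjusted p = 2.10e-04), hypoxia (0.00303) and skin genes (0.0211) were called higher in S1pr1_KO. In that setting only S1pr1_KO replicates 2 and 3 remained, and replicate 3 scored higher in each of these lists. Their scores were 4.85 and 5.52 for cell cycle, 5.51 and 6.74 for hypoxia and -3.19 and 2.85 for skin genes. Complement (camera adjusted p = 0.933) and luminal genes (0.121) also turned there, Clu to log2 0.05, Aldh1a3 to 0.19 and Egln3 to 0.06. In the same setting the camera adjusted p was 0.516 for NK, 0.0942 for endothelial, 0.808 for checkpoint, 0.842 for interferon, 0.359 for macrophage, 0.0648 for red blood cell and 0.917 for ribosomal genes. On log2(FPKM + 1), the camera adjusted p was 0.0511 for cell cycle and 0.285 for checkpoint genes, and Ifit3 was at log2 0.33. With only the 2 groups compared it was 0.0571 for interferon and 0.0550 for luminal genes, and with RLE factors 0.0529 for luminal genes. The 20 lists fell to 10 without C3_KO replicate 3 and 12 without S1pr1_KO replicate 1. Without C3_KO replicate 3, the camera adjusted p was 0.0666 for MHC class II and for macrophage markers, 0.110 for NK markers, 0.226 for complement, 0.237 for checkpoints, 0.940 for interferon, 0.0944 for red blood cell, 0.325 for skin, 0.759 for hypoxia, 0.352 for cell cycle and 0.157 for luminal genes. Without S1pr1_KO replicate 1 it was 0.263 for adipocyte, 0.0834 for NK, 0.161 for complement, 0.314 for checkpoint and for luminal, 0.801 for endothelial, 0.143 for interferon, 0.277 for hypoxia and 0.978 for cell cycle genes. Without C3_KO replicate 2 it was 0.242 for checkpoint, 0.0601 for interferon, 0.0710 for hypoxia, 0.133 for cell cycle, 0.305 for ribosomal and 0.852 for muscle genes. Without S1pr1_KO replicate 2 it was 0.0649 for complement, 0.0616 for checkpoint, 0.0903 for endothelial, 0.103 for hypoxia, 0.0970 for cell cycle, 0.483 for ribosomal and 0.388 for muscle genes. Without C3_KO replicate 1 it was 0.166 for endothelial, 0.204 for luminal and 0.0703 for ribosomal genes, and without C3_KO replicate 4 it was 0.218 for endothelial and for muscle and 0.0562 for luminal genes. Without S1pr1_KO replicate 4 it was 0.559 for luminal, 0.176 for ribosomal and 0.0782 for muscle genes, without S1pr1_KO replicate 3 it was 0.478 for interferon and 0.512 for muscle genes, and without WT replicate 4 it was 0.0509 for luminal genes.

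Of single genes between the knockouts, Cracr2a was 11.0-fold higher in S1pr1_KO at 13.1 ± 12.4 against 1.20 ± 0.397 CPM (SD, n = 4), the smallest p among named genes (edgeR adjusted p = 0.994). Cyp2f2 was at log2 2.70, Tpm3-rs7 at 1.65, Fxyd2 at 2.64 and the nuclease gene Dnase1 at 8.02. Lower in S1pr1_KO were the keratin gene Krt77 at log2 -8.34, the interferon-induced gene Ifi44l at -6.21, Olah, of fatty acid chain release in the mammary gland, at -6.18 and Galnt9 at -5.03. Most of these folds were carried by few libraries. Cracr2a was 25.4, 3.51, 1.41 and 22.1 CPM and Cyp2f2 75.4, 17, 5.02 and 40.4 CPM in S1pr1_KO replicates 1 to 4. Cracr2a, Cyp2f2 and Dnase1 were thus highest in replicates 1 and 4, the S1pr1_KO libraries rich in salivary transcripts. Dnase1 stood at 1440 ± 2780 against 5.58 ± 1.80 CPM (SD, n = 4), with 5615 CPM in S1pr1_KO replicate 1, 146 CPM in replicate 4 and a log2 fold change of 3.34 without S1pr1_KO replicate 1. Fxyd2 stood at 24.8 ± 23.3 against 3.97 ± 2.29 CPM (SD, n = 4). Without S1pr1_KO replicate 1, Fxyd2 was at log2 1.80, Cyp2f2 at 2.00 and Cracr2a at 2.95. In C3_KO, Olah was 14.7 ± 28.5, Galnt9 28.3 ± 49.6, Ifi44l 3.62 ± 6.22 and Krt77 12.7 ± 16.2 CPM (SD, n = 4). Olah was 57.4 CPM in C3_KO replicate 3, with a log2 fold change of -1.19 without it. Galnt9 was 102.5 CPM in C3_KO replicate 2, with -2.03 without it, and Ifi44l 12.9 CPM in C3_KO replicate 4, with -3.43 without it. Krt77 was 34.7 and 15.1 CPM in C3_KO replicates 3 and 4 and at most 0.811 CPM in the other C3_KO libraries. With edgeR, 0 of 30660 genes were called, and 1042 had an unadjusted p under 0.05, 543 higher and 499 lower, against 1533 expected by chance. The lowest edgeR adjusted p was 0.358, for Gm29718, and groups did not overlap for 403 genes, or 1.3%, where chance gives 2.9%. DESeq2 called 121 genes, 61 higher and 60 lower, and limma-voom called 0. The edgeR count was 3 without C3_KO replicate 4, 2 without C3_KO replicate 1 and 1 without C3_KO replicate 3. The median, mean and test differed in sign for the interferon, chemokine, inflammasome, epithelial-mesenchymal and sphingosine-1-phosphate lists.

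Both knockouts were compared with the same WT libraries, and their fold changes were examined together. Glo1 stood at log2 -0.93 in C3_KO and -1.24 in S1pr1_KO, and Dynlt1b at -1.25 and -1.86, with no overlap with WT in either group. The reads of Glo1 and Dynlt1b are uncertain. Cdhr1, Adamtsl2, Ddo, Col4a6, Engase, Cenpx and Ten1 also did not overlap with WT in either knockout. Cdhr1 was 40.6 to 84.3 CPM in S1pr1_KO against 17.5 to 31.4 CPM in WT. Pinc, Bmp1 and Meis1 overlapped with WT in S1pr1_KO. The strains were bred separately, so a difference of both knockouts from WT cannot be told apart from a trait of the WT strain. Ribosomal protein genes were lower in 30 of 30 in both. The covariance of log2 fold changes across genes was 0.460, against 0.199 ± 0.0062 (SD) in 20 simulations of unchanged groups sharing the WT libraries, a difference of 0.26. The simulations drew each gene independently, so their SD leaves out correlation between genes. The correlation was 0.608 against a simulated 0.497, across genes, which are not independent replicates. With the WT libraries split between the comparisons, the covariance was 0.266 to 0.317 and the correlation 0.239 to 0.332. At an unadjusted p under 0.05 in both and in the same direction there were 1125 genes, against 280 simulated, 148 for independent lists and 167 to 315 with split WT libraries. No gene was called in both by edgeR, DESeq2 called 38 in both, limma-voom 5 and limma on log2(FPKM + 1) 1. The edgeR count was 8 without S1pr1_KO replicate 3 and 3 without C3_KO replicate 4. These were all the genes called in C3_KO against WT in those refits. With the CPM filter the covariance was 0.258. With a library left out it ran from 0.431 without C3_KO replicate 4 to 0.836 without WT replicate 2, and was 0.518 without S1pr1_KO replicate 3.

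Some pseudogenes differed by an order of magnitude between libraries. Rpl30-ps10, a ribosomal pseudogene, lay between 28.9 and 43.3 CPM in the WT libraries and between 0.846 and 1.58 CPM in the S1pr1_KO libraries, and was 31.6, 29.4, 30.1 and 1.15 CPM in C3_KO replicates 1 to 4. Its parent gene Rpl30 stood at log2 -0.29 in S1pr1_KO against WT. Glo1-ps, a pseudogene of Glo1, was 2.51 to 5.44 CPM in WT and 0.146 to 0.269 CPM in S1pr1_KO. In C3_KO replicates 1 to 4 it was 0.192, 0.186, 0.165 and 3.65 CPM, and Glo1 was 60.2, 61.9, 59.4 and 83.2 CPM. These pseudogenes were named after their values were seen, and counts of reads that match several places are uncertain.

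**Figure D3:**
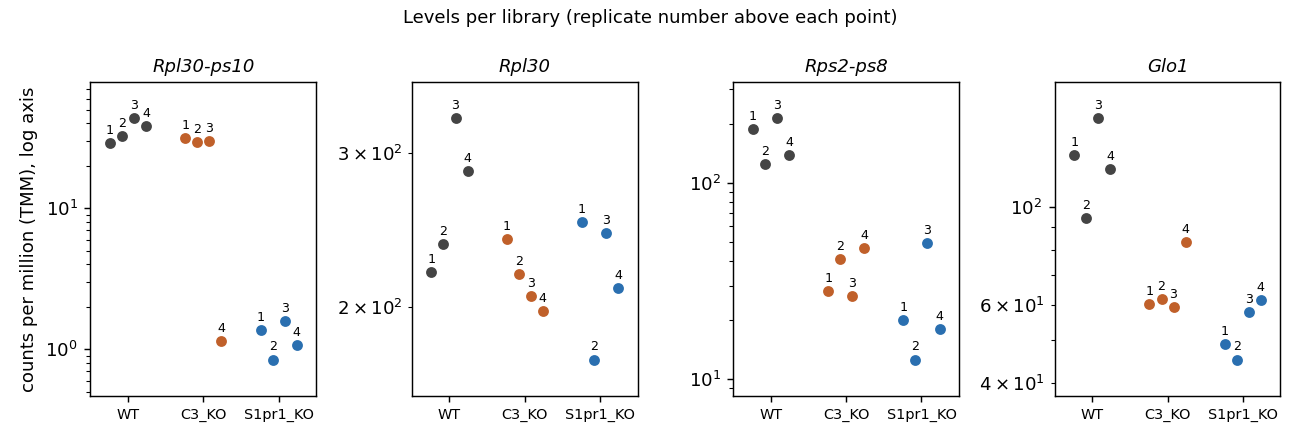
Levels of the pseudogenes Rpl30-ps10 and Rps2-ps8, of Rpl30 and of Glo1 per library, in TMM-scaled CPM on log axes that differ between panels, with the replicate number above each point. Rpl30-ps10 is near 1 CPM in S1pr1_KO and in C3_KO replicate 4 and near 30 CPM elsewhere, while Rpl30 lies between 174 and 329 CPM in all 12 libraries.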

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

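The tests on S1pr1_KO replicate 3, on reads shared with parent genes and on salivary transcripts were chosen after the results were seen, while those on other splits of the libraries and on strain variants had predictions written before their results. A test of a C3_KO label and one of genes shared by both knockouts were added last, with predictions written before their results. Among 405 groups of 4 libraries, 24, or 5.9%, held a library far from the other 3 by Dixon's 95% criterion, where chance gives 5%. C3_KO replicate 2, S1pr1_KO replicate 3, WT replicate 2 and WT replicate 3 stood apart 4 times each, C3_KO replicate 3 did so 3 times, C3_KO replicates 1 and 4 each 2 times and S1pr1_KO replicate 1 a single time.

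Of list scores, in mean log2 CPM, the inflammasome list was 1.54 in C3_KO replicate 2 against 2.85 to 3.02 in the other C3_KO libraries, and the basal list was 4.95 in the same library against 5.34 to 5.4. MHC class II genes were 4.1 in WT replicate 3 against 4.87 to 4.97, and pericyte markers 5.05 against 5.82 to 5.89. Fibroblast and matrix genes were 6.86 in WT replicate 2 against 5.78 to 5.87, and 5.94 in C3_KO replicate 3 against 6.65 to 6.75. Hypoxia genes were 6.74 in S1pr1_KO replicate 3 against 5.47 to 5.67. Salivary markers were 2.22 in C3_KO replicate 1 against -1.95 to -1.44, and mitochondrial genes 10.42 in C3_KO replicate 4 against 11.53 to 11.61.

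Of single genes, in CPM, Pinc was 2.79 in WT replicate 3 against 13.3 to 18 in the other WT libraries, and H2-Oa 0.494 against 1.08 to 1.17. In WT replicate 2, Cd36 was 17.7 against 2.29 to 2.99, Lor 2.5 against 0.385 to 0.502 and Cracr2a 0.86 against 1.36 to 1.4. Glo1 was 83.2 in C3_KO replicate 4 against 59.4 to 61.9, and its pseudogene Glo1-ps was 3.65 there against 0.165 to 0.192. In C3_KO replicate 3, Csn1s2b was 298 against 1.42 to 1.89 and Olah 57.4 against 0.318 to 0.72. In C3_KO replicate 2, St3gal1 was 36 against 57.9 to 62.9 and Btla 0.214 against 1.39 to 1.93, and in C3_KO replicate 1 Prb1 was 0.15 against 0 to 0.00282. In S1pr1_KO replicate 3, Flg was 31.8 against 0.416 to 0.728, Lor 1.24 against 0.256 to 0.305 and Tpm3-rs7 31.3 against 113 to 139. Ucp1 was 48.3 in S1pr1_KO replicate 1 against 0.0702 to 0.127.

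S1pr1_KO replicate 3 lay apart from the other S1pr1_KO libraries on the first component. That it is a mislabelled WT sample was argued against, since of 35 genes that part WT from the other 3 S1pr1_KO libraries, 6 stood at the WT level in it and 29 at the S1pr1_KO level. An exchange with a C3_KO sample stayed undecided, as 0 genes parted C3_KO from the other 3 S1pr1_KO libraries, and 30 and 24 of 44 genes that part S1pr1_KO from WT stood at the S1pr1_KO level in C3_KO replicates 1 and 4. A lower share of cells other than tumour epithelium stayed undecided, as it was the lowest S1pr1_KO library in 7 of 10 lists of other cell types, between the bounds of 8 and 5. Its total of 380.3 M lay above those of the other 3, as predicted for an effect of library size. The 4 libraries with the lowest totals, C3_KO replicate 4 at 237.1 M and S1pr1_KO replicates 1, 2 and 4 at 248.7, 284.1 and 230.4 M, were highest on the first component, at 79.3, 118.4, 128.7 and 77.7 against 17.3 for the next, C3_KO replicate 1. They also had the lowest ribosomal scores, at 9.10, 9.38, 8.91 and 9.04 against 9.57 for the next, C3_KO replicate 3. Among the other 8 libraries size did not follow the pattern. WT replicate 1, the smallest of them at 327.1 M, was lowest on the first component at -114.2 with a ribosomal score of 10.45, and WT replicate 2, the largest at 484.0 M, lay at 4.7 with a score of 10.05. As 3 of the 4 smallest are S1pr1_KO libraries, size cannot be parted from genotype there, and the question was left undecided.

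Some genes were at nearly all-or-none levels across libraries, most of them predicted genes or pseudogenes. If strain variants were the cause, neighbouring genes should share a division of the libraries. Neighbours here are successive genes of the tested set on a chromosome, at any distance from each other. They did so in 16.7% of 6 adjacent pairs, where random orders gave a mean of 6.6% and a 95th percentile of 16.7%. The value met the bound written against strain variants, and a minimum of 20 pairs was added afterwards because 6 pairs cannot decide. A second test, added after that and after some C3_KO levels had been seen, used 54 genes that part S1pr1_KO from WT, 52 of them lower in S1pr1_KO, of which 44 were placed in 28 pairs.

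In that second test, neighbouring genes differed by 0.306 in their position between the S1pr1_KO and WT means in the C3_KO libraries, against 0.396 in random orders with a 5th percentile of 0.347, and 14 of 10000 orders were as low. This is the direction predicted for strain variants passed on in blocks, while neighbours that share reads or regulation could give the same. Distances between the paired genes were not used, so the test does not show that they lie close together. Reads shared with parent genes stayed undecided. The smaller gap between pseudogene and parent was 2.17 log2 units, for Rps2-ps8 at -2.73 against Rps2 at -0.56, but only 2 pairs were measured and both were chosen after their values were seen.

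Salivary transcripts were high in S1pr1_KO replicates 1 and 4. Tissue of another gland in the sample stayed undecided, as 7 of 11 salivary genes had these libraries as their highest 2, out of 66 possible pairs, under the bound of 75%. The bound concerned both libraries together and does not address S1pr1_KO replicate 1 alone. There the salivary score was 9.63 against -0.67 to 2.18 in WT, and the most abundant gene, Bpifa2, took 10.1% of all counts. Whether a few abundant genes distort the scaling stayed undecided, since leaving out the 20 most abundant genes shifted the median log2 fold change of S1pr1_KO against WT by 0 and so decided nothing.

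Other splits of the same libraries gave unadjusted counts, list counts and a covariance as large, so chance was excluded for none of these. A count of 0 genes is reached by every split, so the shares of edgeR calls below say nothing about chance. In C3_KO against WT, 35 of 35 splits called at least the 0 genes edgeR called, where 1909 had an unadjusted p under 0.05 and DESeq2 called 84 and limma-voom 5. At an unadjusted p under 0.05, 10 of 35 gave as many as 1909 genes (highest other 4902), and 32 of 35 moved as many as 9 lists (highest other 25). In S1pr1_KO against WT, 35 of 35 splits called at least 0 genes with edgeR (highest other 2280; DESeq2 901, limma-voom 7828 in the real split), 3 of 35 gave as many as 4743 genes at an unadjusted p under 0.05 (highest other 9414) and 20 of 35 moved as many as 14 lists (highest other 28). Between the knockouts, 35 of 35 called at least 0 with edgeR (highest other 1361; DESeq2 121, limma-voom 0), 24 of 35 gave as many as 1042 genes at an unadjusted p (highest other 8003) and 15 of 35 moved as many as 20 lists (highest other 28). The covariance of 0.460 was reached in 10 of 100 divisions of the 12 libraries (highest other 0.703), and 100 of 100 divisions had at least the 0 genes called in both by edgeR (highest other 0; DESeq2 38, limma-voom 5), which again says nothing. For the genes at an unadjusted p under 0.05 in both and in the same direction, 9 of 100 divisions gave as many as 1125 (highest other 5322). The split with 2280 and 9414 genes put S1pr1_KO replicate 3 with WT replicates 1, 3 and 4. It keeps 6 of the 8 libraries on the side of their genotype, and its cause was not tested.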

How the results depend on the processing

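The 2 alternatives that left out predicted genes and pseudogenes, or libraries rich in milk or salivary transcripts, were chosen after the results were seen. No paired analysis was possible because replicate numbers follow accession order and the labels give no pairing. Where no cause is given, the cause was not tested. edgeR called 0 genes in each comparison, at unadjusted counts of 1909, 4743 and 1042. In C3_KO against WT, DESeq2 called 84, limma-voom 5 and log2(FPKM + 1) 1. In S1pr1_KO against WT, DESeq2 called 901, limma-voom 7828, with a weight of 0.28 for S1pr1_KO replicate 3, no filter 10, the CPM filter 23, only the 2 groups compared 68, log2(FPKM + 1) 41, log2(FPKM + 0.1) 39 and log2(FPKM + 1) with no filter 1. Between the knockouts, DESeq2 called 121. In both knockouts, DESeq2 called 38, limma-voom 5 and log2(FPKM + 1) 1. With a library left out, counts ran from 0 to 8 in C3_KO against WT (8 without S1pr1_KO replicate 3, 3 without C3_KO replicate 4), 0 to 1330 in S1pr1_KO against WT (1330 without S1pr1_KO replicate 3, 32, 9 and 2 without C3_KO replicates 4, 1 and 3, 1 without S1pr1_KO replicate 2), 0 to 3 between the knockouts (3, 2 and 1 without C3_KO replicates 4, 1 and 3) and 0 to 8 in both. Both added alternatives called 0 genes with edgeR in each comparison, at unadjusted counts of 1022, 2463 and 516 of 17705 genes and 1330, 2204 and 480 of 32280. C3 in C3_KO against WT ran from -0.98 to -0.32 with a library left out. S1pr1 in S1pr1_KO against WT ran from -0.49 to 0.12, and turned to 0.39 with limma-voom, 0.01 in all 3 FPKM settings, 0.12 without WT replicate 2, 0.08 without S1pr1_KO replicate 3 and 0.01 without S1pr1_KO replicate 4. Between the knockouts, Ifit3 turned to 0.33 with log2(FPKM + 1), 0.38 with log2(FPKM + 0.1), 0.33 with no filter on FPKM and 0.23 without C3_KO replicate 1 (-0.92 to 0.23 with a library left out), Aldh1a3 to 0.14 without C3_KO replicate 3 (-1.73 to 0.14), Ucp1 to -1.74 without S1pr1_KO replicate 1 (-1.74 to 6.81) and Actn3 to 0.56 without C3_KO replicate 2 (-5.01 to 0.56). Without the libraries rich in milk or salivary transcripts, Clu turned to 0.05, Aldh1a3 to 0.19, Egln3 to 0.06 and Ucp1 to -2.18. Camera moved 0 lists in each comparison with an estimated correlation, and fry 0, against 9, 14 and 20 with the preset correlation, which takes members of a list as nearly independent. On log2(FPKM + 1), 8 lists moved in S1pr1_KO against WT. With a library left out, 6 to 16, 12 to 18 and 10 to 21 lists moved (16 and 6 without C3_KO replicates 1 and 2 in C3_KO against WT, 10 without C3_KO replicate 3 and 12 without S1pr1_KO replicate 1 between the knockouts). Between the knockouts, list directions turned for interferon genes without C3_KO replicate 2 (camera adjusted p = 0.0601) or 3 (0.940), cell cycle without C3_KO replicate 3 (0.352) or S1pr1_KO replicate 1 (0.978) and hypoxia without C3_KO replicate 3 (0.759). The lowest camera adjusted p with a library left out was 6.01e-07 for interferon, 8.06e-06 for cell cycle and 6.82e-06 for hypoxia genes. Without the libraries rich in milk or salivary transcripts they turned for complement (camera adjusted p = 0.933), luminal (0.121), cell cycle (2.10e-04), hypoxia (0.00303) and skin genes (0.0211), and for salivary genes in S1pr1_KO against WT (0.416). Only S1pr1_KO replicates 2 and 3 remained of that group in this setting. The covariance was 0.317, 0.278, 0.266, 0.275, 0.297 and 0.289 with split WT libraries, 0.258 with the CPM filter and 0.463 with RLE factors, and ran from 0.431 to 0.836 with a library left out (0.836 without WT replicate 2, 0.598 without WT replicate 4, 0.604 without C3_KO replicate 2). Upper quartile factors shifted the median log2 fold change of all genes to 0.128 in C3_KO and 0.146 in S1pr1_KO, against 0.053 and 0.026 with TMM. Of the values of moved lists and named genes, leaving aside C3 in C3_KO against WT and S1pr1 in S1pr1_KO against WT, 3570 kept direction and side of the threshold, 106 came to pass it, 173 no longer passed it and 22, all given above beside the 7 of S1pr1, turned in direction. Of the values that came to pass, 40 did so with DESeq2, 34 with limma-voom and 26 without S1pr1_KO replicate 3.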

Other observations

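Both tests below were chosen after the levels of the targeted genes had been seen. Because S1pr1 is abundant in blood vessels and C3 in stroma, each was set against the markers of those cells, as log2 CPM minus the mean of the list. In whole tumours such a ratio also moves with the markers, so it does not measure a level per cell. As Cre acts mainly in mammary epithelium, a loss in these other cells is not what the design predicts.

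The hypothesis that S1pr1 is lower per endothelial cell in S1pr1_KO was tested first. S1pr1 minus the other blood endothelial markers was -1.78 ± 0.51 in S1pr1_KO against -0.97 ± 0.31 in WT (SD, n = 4; exact permutation p = 0.0857), with library values of -1.86, -1.06, -2.24 and -1.96 against -0.76, -0.66, -1.17 and -1.29. The test did not decide. S1pr1 itself was at log2 -0.17 while the endothelial list had a median of 0.70, so the markers moved more than S1pr1. The hypothesis that C3 is lower per fibroblast in C3_KO was tested in the same way. C3 minus the fibroblast and matrix genes was -0.65 ± 0.35 in C3_KO against 0.40 ± 0.98 in WT (SD, n = 4; exact permutation p = 0.0286), the smallest p that 4 against 4 libraries allow. Adjusted over both hypotheses, the permutation p was 0.0572, which did not pass. Library values were -1.17, -0.43, -0.57 and -0.43 against 1.69, -0.38, 0.62 and -0.34. C3 itself was at log2 -0.76 and the fibroblast list had a median of 0.48, so both contributed to the difference.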
